A study of Mus musculus with 2 samples.

How the data were processed

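The series holds 2 single-cell RNA libraries from the aortic root and ascending aorta of 16-week-old Fbn1C1041G/+ mice, 1 from mice given GLPG0187 and 1 from mice given vehicle. Per the labels' protocols, aortas of male and female mice were pooled in equal numbers within each group, digested with enzymes, sorted to exclude debris and made into libraries with the 10x Genomics 3' version 3 chemistry. The number of animals in each pool is not given in the sources used here. Groups were taken from the treatment label of each sample, and each group holds 1 library.

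The deposited values are whole numbers per gene and cell on a depth-corrected scale, treated here as a score and not as UMI counts. Totals per cell lay between 12078 and 16719, with a coefficient of variation of 5.69% in the GLPG0187 library and 5.81% in the vehicle library, although the number of genes detected per cell ranged from 1868 to 5672. Totals that even do not occur in raw droplet data, so the depth of the cells had been adjusted before deposit. Cell Ranger, Seurat and the genome build mm10 are named, without versions or roles, per the submitters' processing notes. How the adjustment, the cell filters and the gene filter were done is not given in the sources used here. The design fixed before the data were examined assumed UMI counts, with sums of counts and Poisson intervals. Because the files hold depth-corrected values, no count model and no Poisson interval was used outside the simulation described below. The raw depth of each cell is unknown, and a difference in total RNA per cell could not be seen.

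The cell filter kept cells with at least 200 genes and at most 20% mitochondrial values. It removed 0 cells, since the highest mitochondrial share in the files was 5.20%. Doublets were called per library with Scrublet in scanpy 1.11.5 at its automatic threshold, and 48 cells (1.09%) of the GLPG0187 library and 16 cells (0.540%) of the vehicle library were removed. Doublets are harder to find in values whose totals have been evened out, so some may remain. The analysis used 4349 and 2945 cells, with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9 in Python 3.11.15, and matplotlib 3.10.9 for plots.

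For clustering, values were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen without mitochondrial, ribosomal protein, Xist, Tsix and Y-linked genes. Genes were scaled over both libraries together, reduced to 30 principal components and joined by 20 nearest neighbours with shared-neighbour weights. Leiden clustering was run at resolution 0.5. A cluster was named "X-like" when at least 3 of a class's fixed markers, and 75% of them, were detected in 25% of its cells and lay over 3 times above the median of the clusters, and when its 10 leading genes held no more markers of another class than of its own. Smooth muscle cell (SMC) lineage cells were clustered again in the same way, and a sub-cluster was called modulated SMC-like when at least 50% of the modulated SMC markers lay 1.5-fold above the other SMC-lineage cells and Myh11 lay below them. The markers of 18 cell classes, the gene lists, the design and most alternatives were fixed before the data were examined. The naming thresholds, the rule for sub-clusters and the tolerances used to call a value moved were set after the data had been seen.

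Within each class, values were summed per library and divided by the library's total for that class, and log2 ratios of GLPG0187 over vehicle were taken after adding 1 to each sum. Genes with summed values of at least 100 over both libraries were measured. Genes at least 1.5-fold higher or lower were counted by size only. The fixed lists were contractile, modulated SMC, fibrillar collagen, elastic fibre, basement membrane, proteoglycan, matrix protease, integrin, focal adhesion, TGF-beta target, mTORC1 metabolic, immediate early, heat shock, unfolded protein and integrated stress, inflammatory, interferon, osteochondrogenic, Notch, ribosomal protein, mitochondrial genome, resident macrophage, inflammatory macrophage, MHC class II and endothelial activation. A list with at least 3 measured members was described by its median log2 ratio, by its members with a log2 ratio of at least 0.32 in either direction, and, for the main lists, by the percentile of its median among 10000 random lists of the same size drawn from the same 20 expression bins. A percentile describes these libraries and is not a test. Shares of cells carry exact Clopper-Pearson 95% intervals, and differences of shares carry intervals built from those of both libraries. The intervals of shares cover counting error only, and where 0 cells were seen a share of up to 3 cells of the total is allowed. An interval of a list median holds 95% of the medians of 2000 random redraws of the list's measured members. No p-value was computed, because cells are not replicates.

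As a description of separate animals within a pool, all comparisons were repeated in cells with Xist and no Y-linked gene above 0 (Xist-only) and in cells with a Y-linked gene and no Xist above 0 (Y-only). Xist-only cells made up 26.2% of the GLPG0187 and 32.1% of the vehicle library and Y-only cells 61.7% and 56.5%, which is unequal although the labels give equal numbers of animals. These groups share a library preparation and are not replicates of it. The rule for named genes took, in SMC-like cells, up to 12 genes each with the largest and smallest log2 ratio among genes with summed values of at least 200, at least 50 in the higher library after scaling to 1000000, a difference of at least 1.5-fold, and the same direction in Xist-only cells, in Y-only cells and under median-of-ratios scaling. Mitochondrial, ribosomal protein, haemoglobin, sex-specific and unnamed genes were left out of that ranking. In fibroblast-like, endothelial-like and macrophage-like cells the rule took 5 and 5, it always named 22 genes in SMC-like cells, and it took up to 4 members from each list. Not every gene taken by the rule is printed. Gene symbols are those of the files. Positions are from the GENCODE vM21 annotation of GRCm38, the assembly also called mm10, in which 154 of 156 named symbols were found.

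The comparison was tested on simulated data with known answers, using 10748 genes of the SMC-like comparison. All 62 genes set to a 1.5-fold change were recovered in the right direction, 29 of them at 1.5-fold or more, and all 60 genes set to 2-fold and all 63 set to 4-fold were recovered at 1.5-fold or more. Of 10563 unchanged genes, 39 came out at 1.5-fold or more. The simulation drew Poisson values around the summed values of the class, although the files do not hold counts. It leaves out variation between cells, animals and libraries. The 39 genes are therefore not an error rate for the real comparison. Alternatives tried were other cell filters, doublets kept, Leiden resolutions 0.3 and 1.0, scaling within each library before clustering, clustering without contractile and modulated SMC list genes, Xist-only and Y-only cells, other scalings, other minimum values, cells thinned to 2000, means over cells, and means over list members. Added after seeing the data were SMC-like cells without modulated cells, shares without clusters 1 and 6, and SMC-lineage cells without a sub-cluster found in the vehicle library alone. In alternatives that repeated the clustering, names were given without the check of the 10 leading genes. Comparisons within Schwann-like and dendritic-like cells were left out because they held under 100 cells per library. Raw reads were not used here.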

Results

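Single-cell RNA profiles were compared between aortas of Marfan syndrome mice given GLPG0187, described by the submitters as an inhibitor of integrin alpha-v, and aortas of mice given vehicle. Fbn1C1041G/+ mice carry a mutation in fibrillin-1, a component of elastic fibres. The aortic root and ascending aorta were collected at 16 weeks of age, and the aortas of each group were pooled into 1 library. The GLPG0187 library held 4397 cells and the vehicle library 2961 cells, both over the same genes. Depth-corrected values summed to a median of 14942 per cell (range 12135 to 16719) in the GLPG0187 library and 14806 (12078 to 16187) in the vehicle library. The medians of genes detected per cell were 3773 and 3788. With 1 library per group, no difference between the groups could be tested, and treatment cannot be separated from the animals, the dissection or the library preparation. Intervals of shares are 95% and cover counting error only, and gene counts are by size only, not of genes that changed. Gene values are mean depth-corrected values per cell.

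The first comparison asks which cell types the aortas held. SMC-like cells, the contractile cells of the aortic wall, made up 38.7% (37.2 to 40.1, 1681 of 4349 cells) of the GLPG0187 library and 28.7% (27.1 to 30.4, 845 of 2945 cells) of the vehicle library, a difference of 9.96 percentage points (7.75 to 12.2). SMC-like cells joined 2 clusters, of which cluster 0 made up 29.8% and 18.5%. The other, cluster 3, led by Tnnt2, Timp4 and Nrgn, made up 8.81% and 10.2%, with an interval of the difference (-2.80 to 0.00589) that spans 0. Fibroblast-like cells made up 24.8% (23.6 to 26.1) and 30.2% (28.5 to 31.8). Macrophage-like cells made up 7.84% (7.06 to 8.68) and 6.04% (5.21 to 6.97). Endothelial-like cells were at 3.70% and 3.53%, which counting error alone does not separate. Schwann-like cells, led by the pigment cell gene Dct, were at 0.621% (27 cells) and 1.46% (43 cells), and dendritic-like cells at 0.391% (17 cells) and 0.374% (11 cells). Fibroblast-like cells included a cluster led by Il6, Adamts4 and Ptgs2 and a small cluster led by Hp, Saa3 and Lcn2, which are stress or immune genes. The naming thresholds kept 2 clusters out of every class. Cluster 1, led by Prss35, Npy and Tbx20, held 20.3% of the GLPG0187 library and 24.1% of the vehicle library, and cluster 6, led by the cartilage genes Chad, Comp and Col2a1, held 3.68% and 5.60%. The SMC-like share was higher in the GLPG0187 library among Xist-only cells (41.5% and 27.2%) and among Y-only cells (39.4% and 30.9%). The macrophage-like share was higher among Y-only cells (8.90% and 6.97%) but not among Xist-only cells (3.86% and 3.92%). Digestion and sorting came before the cells were counted and can set all of these shares.

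**Figure D1:**
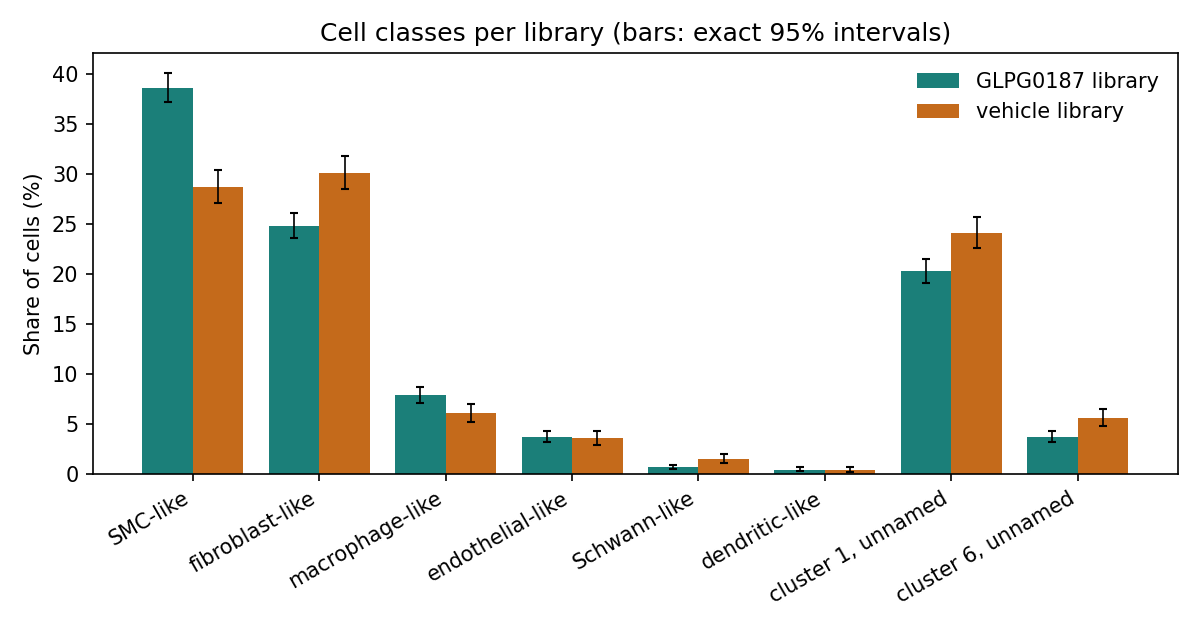
Share of cells in each class or unnamed cluster (vertical axis, percent of the library's cells) in the GLPG0187 and vehicle libraries, with exact 95% intervals as error bars. SMC-like cells stand at 38.7% and 28.7%, and fibroblast-like cells at 24.8% and 30.2%.

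Modulated SMC-like cells, which held little Myh11 and carried matrix and fibroblast genes, were a smaller part of the SMC lineage in the GLPG0187 library. They made up 4.52% (3.58 to 5.63, 76 of 1681 cells) of SMC-lineage cells there and 18.2% (15.7 to 21.0, 154 of 845 cells) in the vehicle library, a difference of -13.7 percentage points (-16.6 to -10.9), or a share 4.03-fold higher in the vehicle library. The gap was smaller with genes scaled within each library before clustering, where more cells were called modulated (15.8% and 25.5%), and with doublets kept (3.77% and 14.1%). The share was also lower among Xist-only cells (2.75%, 13 of 473, and 10.9%, 28 of 257) and among Y-only cells (4.92%, 52 of 1057, and 21.4%, 110 of 515). Counted over all cells, modulated cells made up 1.75% and 5.23%. When the sub-clusters were made without the genes of the contractile and modulated SMC lists, the shares were 4.34% and 17.6%. Inside the modulated cells, the mean of Myh11, the smooth muscle myosin heavy chain, was 10.7 and 10.5, against 52.2 and 45.3 in the other SMC-like cells and 1.23 and 0.748 in fibroblast-like cells. Tnfrsf11b, which encodes osteoprotegerin, was above 0 in 84.2% and 88.3% of modulated cells and in 40.9% and 42.5% of other SMC-like cells. The shares were 40.2% and 41.5% in cluster 1, 19.3% and 19.6% in fibroblast-like and 3.52% and 2.25% in macrophage-like cells. Median genes detected were 4140.5 and 4142.5 in modulated cells and 3179 and 3061.5 in macrophage-like cells. Low Myh11 and markers that include Tnfrsf11b were part of the naming rule, so these values do not back the name. SMC-like cells without the modulated ones made up 36.9% of the GLPG0187 library and 23.5% of the vehicle library.

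**Figure D2:**
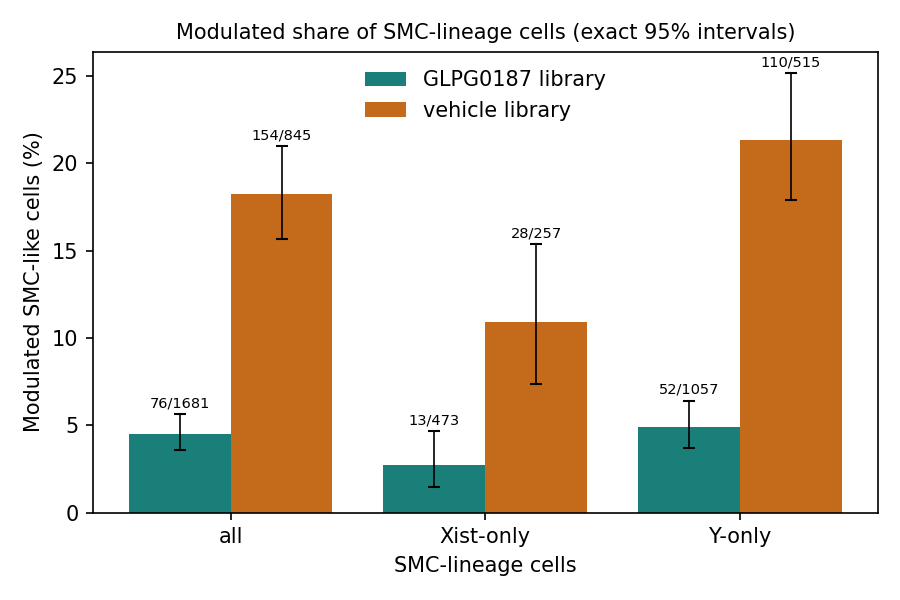
Modulated SMC-like cells as a percent of SMC-lineage cells (vertical axis) in the GLPG0187 and vehicle libraries, for all cells, Xist-only cells and Y-only cells, with exact 95% intervals and cell numbers. The shares were 4.52% and 18.2% for all cells, 2.75% and 10.9% for Xist-only cells, and 4.92% and 21.4% for Y-only cells.

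Contractile genes were slightly higher in SMC-like cells of the GLPG0187 library. Members of a list are counted here as higher or lower when their log2 ratio was at least 0.32 in size, and as between otherwise. Of 16 measured contractile members, 3 were higher, 0 lower and 13 between, with a median log2 ratio of 0.27 (percentile 100 among random lists). Cnn1, which encodes calponin, had means of 23.2 and 17.4 in the GLPG0187 and vehicle libraries (log2 ratio 0.42), Myh11 50.3 and 39.0 (0.37), smooth muscle actin Acta2 299 and 251 (0.25), and Tagln 247 and 220 (0.17). Without the modulated cells the median was 0.12 and 0 of the 16 members were higher. In other cells the contractile list had medians of 0.15 in fibroblast-like cells (2 of 15 higher), 0.73 in macrophage-like cells (-0.64 in Xist-only ones), 0.23 in cluster 1 and -0.13 in endothelial-like cells (1 higher, 1 lower and 11 between).

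The modulated SMC list ran the other way in SMC-like cells, with 10 of 15 members lower in the GLPG0187 library, 1 higher and 4 between, and a median log2 ratio of -0.49 (percentile 0). Vcam1, an adhesion molecule for white blood cells, had means of 2.26 and 4.68 (-1.05), Tnfrsf11b 1.06 and 2.11 (-0.99), the protease inhibitor gene Timp1 0.813 and 1.84 (-1.18), Fn1, which encodes fibronectin, 11.6 and 14.6 (-0.34), and the transcription factor gene Klf4 1.51 and 1.79 (-0.24). Lgals3, at 1.02 and 0.741, was higher (0.47). Without the modulated cells the median was -0.20, and Vcam1 stood at -0.30, Tnfrsf11b at -0.20, Timp1 at 0.08 and Fn1 at 0.16. Of the fixed fibroblast markers, 6 of 12 were lower, 1 higher and 5 between in SMC-like cells, with a median of -0.35 (-0.11 in Xist-only and -0.18 in Y-only cells), and the cartilage or valve markers had a median of -0.57 over 4 measured genes.

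Integrin genes differed little between the libraries. In SMC-like cells 1 of 11 measured members was higher, 0 lower and 10 between, with a median log2 ratio of 0.10 (percentile 98.8). Itgav, which encodes the alpha-v subunit, had means of 1.14 and 1.20 (-0.07, or 0.08 without modulated cells) and was above 0 in 66.3% and 66.5% of SMC-like cells. The means of its partners were 28.0 and 25.1 for Itgb1 (0.16), 0.477 and 0.419 for Itgb3 (0.19), and 4.22 and 4.60 for Itgb5 (-0.12, or 0.07 without modulated cells). Itga5, the fibronectin receptor subunit, was the higher member, at 2.73 and 1.96 (0.48). Itgb3 was above 0 in 36.9% and 33.6% of SMC-like cells, with median genes detected of 4023 and 4137, and in 0.567% and 0.281% of cluster 1 cells, with 3828 and 4047. Of the focal adhesion list, 1 of 17 members was higher and 16 lay between, with a median of 0.15, and the member was the caveolin gene Cav1 (5.74 and 4.50, log2 ratio 0.36).

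Fibrillar collagen and basement membrane genes of SMC-like cells were mostly close between the libraries. For fibrillar collagens and their processing enzymes, 0 of 15 members were higher, 3 lower and 12 between, with a median of 0.03 (percentile 84.4) and a mean of -0.04. Col1a1 had means of 5.71 and 5.81 (-0.02), Col3a1 16.1 and 13.6 (0.25), and Col8a1 0.677 and 1.01 (-0.57). For elastic fibre genes, 5 of 17 were lower and 12 between, with a median of -0.12, or -0.01 without modulated cells. Eln, which encodes elastin, had means of 13.9 and 14.9 (-0.09), Fbn1 2.11 and 2.57 (-0.28), and Fbln2 0.391 and 0.757 (-0.95, or 0.34 without modulated cells). Basement membrane genes had a median of 0.12, with 2 of 14 lower and 12 between, among them Lama4 (0.907 and 0.744, 0.29) and Lamb1 (0.0446 and 0.0923, -1.05). Proteoglycan genes had a median of -0.12, with 1 of 10 higher and 3 lower, including Lum (2.29 and 3.37, -0.56) and Ogn (14.5 and 11.4, 0.35). Matrix protease genes had a median of -0.22 (0.14 in Xist-only cells), with 2 of 12 higher and 5 lower. Mmp2, a gelatinase, had means of 0.459 and 0.721 (-0.65) and Mmp3 0.648 and 1.04 (-0.68), but in Xist-only cells their log2 ratios were 0.18 and 0.55.

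TGF-beta target genes, a pathway that latent TGF-beta reaches through alpha-v integrins, were mixed. Of 14 members, 5 were lower in SMC-like cells of the GLPG0187 library, 1 higher and 8 between, with a median of -0.13 (percentile 0.11), which was 0.14 in Xist-only and -0.26 in Y-only cells. The list also holds the genes of TGF-beta itself, Tgfb1, Tgfb2 and Tgfb3. Tgfb3 was its only higher member and Tgfb1 was among the lower ones, so the counts do not describe targets alone. Ctgf, a connective tissue growth factor gene, had means of 25.2 and 43.5 (-0.79), Tgfb1 0.428 and 0.685 (-0.68), Tgfb2 2.98 and 2.51 (0.25) and Tgfb3 1.58 and 1.23 (0.37). Without modulated cells the median was 0.05, while Ctgf stayed at -0.67. Metabolic genes of the mTORC1 pathway had a median of 0.01 (percentile 86.5), with 1 of 22 higher, 2 lower and 19 between. The serine synthesis genes Psat1 (0.0518 and 0.0769, -0.58, but 0.31 in Xist-only cells and 0.19 without modulated cells) and Phgdh (0.120 and 0.175, -0.55) were the lower ones, and the asparagine synthetase gene Asns (0.0535 and 0.0331, 0.66) was the higher one.

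**Figure D3:**
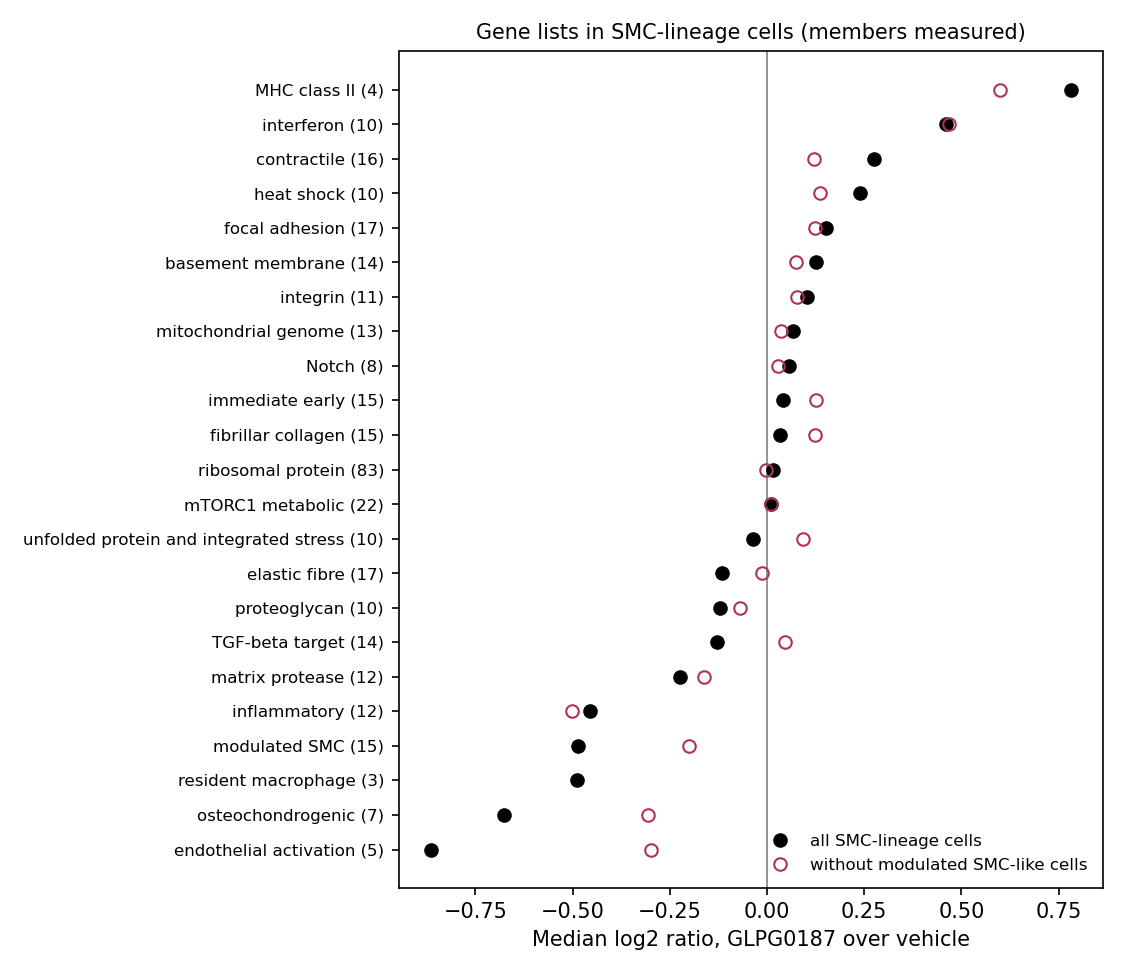
Median log2 ratio of GLPG0187 over vehicle (horizontal axis) for each fixed gene list in SMC-lineage cells, with the number of measured members, for all SMC-lineage cells (filled points) and without modulated SMC-like cells (open points). The modulated SMC list moved from -0.49 to -0.20 and the contractile list from 0.27 to 0.12 when modulated cells were left out.

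Immune and cartilage genes also differed within SMC-like cells. Interferon genes had a median of 0.46, with 7 of 10 members higher and 0 lower, including Ifi27l2a (0.992 and 0.604, 0.72) and Ifit3 (0.213 and 0.0805, 1.39). Ifit3 was above 0 in 5.71% and 6.51% of SMC-like cells, so its higher mean did not come from a larger share of cells. Ifit3 turned with the clustering, to -0.17 at resolution 1.0 and -0.28 with scaling within each library. All 4 measured MHC class II genes were higher, with a median of 0.78, among them Cd74 (0.615 and 0.322, 0.93), but the median was 1.75 in Xist-only and 0.35 in Y-only cells, where H2-Aa stood at -0.022. Inflammatory genes had a median of -0.46, with 6 of 12 lower and 2 higher, but the medians were -0.07 in Xist-only cells and -0.16 in Y-only cells. The chemokine gene Cxcl1 had means of 0.350 and 0.832 but was above 0 in 6.78% and 6.04% of cells. Means were 0.0708 and 0.0166 for Ccl7 (2.01) and 0.0440 and 0.0959 for Il6 (-1.12, but 0.10 in Xist-only cells and 0.30 with doublets kept). Osteochondrogenic genes had a median of -0.67, with 7 of 7 measured members lower, among them Spp1 (0.137 and 0.425, -1.63) and Comp (0.474 and 1.23, -1.37). Without modulated cells that median was -0.31, with 3 of 7 lower. Spp1 was above 0 in 4.40% and 17.9% of SMC-like cells. In fibroblast-like cells it was above 0 in 6.67% and 15.4%, with means of 0.872 and 15.2. Whether RNA from other cells contributed to the values in SMC-like cells was not tested. The endothelial activation list had a median of -0.86 over 5 measured members, or -0.30 without modulated cells, with Icam1 at 0.0857 and 0.178 (-1.05). The resident macrophage list had a median of -0.49 over 3 measured members, but 0.43 in Xist-only cells. Heart muscle transcripts were lower too. Fixed cardiomyocyte markers had a median of -2.04 in SMC-like cells but 0.18 in Y-only ones, and Myh6, a heart myosin gene, had means of 0.0232 and 0.355, from 0.654% and 1.18% of cells.

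Stress and housekeeping lists had small median differences between the libraries in SMC-like cells, and the heat shock median was the largest in size. By members counted as higher or lower, the immediate early list was the furthest apart, with members in both directions. Heat shock genes had a median of 0.24 (0.54 in Xist-only and 0.08 in Y-only cells), with 0 of 10 higher, 1 lower and 9 between, and the lower member was Dnajb1 (1.24 and 2.06, -0.73). Immediate early genes, which respond to tissue handling, had a median of 0.04 (0.24 in Xist-only and -0.09 in Y-only cells), with 4 of 15 higher and 2 lower, including Fos (19.9 and 12.2, 0.70) and Jun (4.19 and 5.80, -0.47). The unfolded protein and integrated stress list had a median of -0.04, which turned to 0.01 under median-of-ratios scaling, with all 10 members between. The Notch list had a median of 0.06 with all 8 members between, the ribosomal protein list one of 0.01 over 83 genes, and the mitochondrial genome list one of 0.07 over 13 genes. The inflammatory macrophage list had under 3 measured members in SMC-like cells.

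Of 10767 measured genes in SMC-like cells, 60 were at least 1.5-fold higher and 306 at least 1.5-fold lower in the GLPG0187 library. Of the 306 lower genes, 226 (73.9%) were at least 1.5-fold higher in modulated than in other SMC-like cells, as were 13.5% of all measured genes. Both libraries were pooled for that comparison. Modulated cells numbered 76 and 154 and other SMC-like cells 1605 and 691. A gene lower throughout the GLPG0187 library thus leans towards being higher in modulated cells. The 73.9% therefore does not show that modulated cells account for the lower genes. Without the modulated cells, 169 of the 306 and 44 of the 60 still met the 1.5-fold mark in the same direction. Only 8 higher genes met the rule for named genes. Among them were Zbtb16, a transcription factor gene (1.20 and 0.510, 1.23), the circadian repressor gene Nr1d1 (1.22 and 0.612, above 0 in 58.5% and 37.6% of cells), Itih4 (2.24 and 1.29, 0.80), Ifi27l2a, Fos and Mindy3 (1.05 and 0.682, 0.62). Of 36 lower genes that met it, the 12 with the smallest ratios were Comp, Nrgn (0.512 and 1.31, -1.35), Cxcl1, Timp1, Cd34 (0.858 and 1.82, -1.08), Crispld1 (0.700 and 1.47, -1.07), Vcam1, Tnfrsf11b, Lamc3 (1.29 and 2.55, -0.98), Fbln2, Nrp1 (0.615 and 1.14, -0.88) and Cebpd (1.48 and 2.73, -0.88). In GRCm38, Itgav lies on chromosome 2 (83724397 to 83806916), Myh11 on chromosome 16 (14194535 to 14291372), Vcam1 on chromosome 3 (116109949 to 116129688), Tnfrsf11b on chromosome 15 (54250619 to 54278484), Zbtb16 on chromosome 9 (48654297 to 48836222) and Nr1d1 on chromosome 11 (98767932 to 98775333), and all 6 are annotated as protein-coding.

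Fibroblast-like cells of the GLPG0187 library held more interferon, antigen-presentation and inflammatory transcripts. Of the interferon list 11 of 12 members were higher (median log2 ratio 0.78), of MHC class II 5 of 6 (1.56), of the inflammatory list 9 of 12 (0.64) and of the immediate early list 7 of 15 (0.30), and no member of these was lower. Fixed macrophage markers, which share cells with MHC class II and chemokine genes, were higher too, in 3 of 4 (median 0.43). Iigp1, an interferon-induced GTPase gene, had means of 2.30 and 0.491 (2.22), the chemokine genes Cxcl2 1.08 and 0.238 (2.17) and Ccl7 1.16 and 0.337 (1.77), Tnfaip2 0.765 and 0.230 (1.73) and Tnfaip6 2.05 and 0.633 (1.69, but 0.032 in Xist-only cells). Lower were Spp1, which encodes osteopontin (0.872 and 15.2, -4.13, or -1.08 in Xist-only cells, above 0 in 6.67% and 15.4% of cells, and a leading gene of the small Hp, Saa3 and Lcn2 cluster), Chil1 (0.850 and 2.69, -1.66), Ptn (1.54 and 3.50, -1.18), the glucocorticoid-induced gene Tsc22d3 (2.55 and 4.80, -0.91, or -0.16 in Xist-only cells) and Comp (2.95 and 5.25, -0.84). Of 10312 measured genes, 242 were at least 1.5-fold higher and 130 lower, from 1080 and 888 cells.

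Endothelial-like cells showed large differences in antigen-presentation genes, on 161 and 104 cells. The class mixes lymphatic and blood vessel endothelium, since 47.8% and 46.2% of its cells held at least 3 lymphatic markers. All 6 measured MHC class II genes were higher in the GLPG0187 library (median 3.19), with means of 4.68 and 0.433 for H2-Aa (3.39) and 12.7 and 1.19 for Cd74, the invariant chain gene (3.39). Cells with at least 3 of these genes above 0 made up 51.6% (43.6 to 59.5) and 5.77% (2.15 to 12.1), against 8.98% and 1.80% of fibroblast-like cells, with median genes detected of 3113 and 2983 in the former and 3408.5 and 3423 in the latter. Interferon genes were higher in 11 of 11 (1.53), and the endothelial activation list in 4 of 8, with 2 lower (0.33, but -0.04 in Y-only cells). Immediate early genes were lower in 12 of 15 (-0.53, with -0.08 in Xist-only and -1.03 in Y-only cells) and heat shock genes in 6 of 10 (-0.35). The chemokine gene Cxcl9 had means of 8.02 and 0.317 (4.60) from 8.07% and 5.77% of cells. Cxcl10 (mean 1.78) and Ubd (1.48) were each above 0 in only 4.97% of endothelial-like cells of the GLPG0187 library. Both were listed at 0 in the 104 endothelial-like cells of the vehicle library. Lower were Tcim (0.484 and 1.91, -1.99), the lipoprotein receptor gene Scarb1 (0.416 and 1.38, -1.73), Enpp2 (0.745 and 2.11, -1.51, but 0.06 at resolution 1.0), Rflnb (0.776 and 2.18, -1.51) and Rgs5 (0.988 and 2.71, -1.47, but -0.066 in Xist-only and -4.48 in Y-only cells). Fixed fibroblast markers had a median of 0.41 in these cells. Of 4881 measured genes, 253 were at least 1.5-fold higher and 179 lower.

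Macrophage-like cells of the GLPG0187 library held more interferon transcripts, with 12 of 12 list members higher and a median of 1.99, on 341 and 178 cells. Rsad2, which encodes the antiviral protein viperin, had means of 7.93 and 0.360 (4.42), Iigp1 2.38 and 0.124 (4.18), Ifit2 2.34 and 0.174 (3.68), Cmpk2 0.812 and 0.0730 (3.35) and Ifit1 3.04 and 0.303 (3.27). In Xist-only cells the list median was lower, at 1.03, with Ifit1 at 1.05 and Cmpk2 at 1.11. SMC contractile genes were also higher in these cells, in 11 of 13. Acta2 was above 0 in 98.5% and 90.4% of them and Myh11 in 48.7% and 42.1%. In fibroblast-like cells Acta2 was above 0 in 98.8% and 94.8%, so SMC transcripts were listed widely outside the SMC lineage. All 7 MHC class II genes were higher (0.80). Of the resident macrophage list 3 of 8 were lower and 5 between (-0.29), and of the inflammatory macrophage list 3 of 9 were higher and 2 lower, with a median of -0.14 and a mean of 0.31. Lower were Igfbp5 (0.223 and 1.20, -2.44), Cxcl9 (0.771 and 3.09, -2.02, but above 0 in 7.04% and 5.06% of cells), the glucocorticoid-induced genes Fkbp5 (0.534 and 1.42, -1.43) and Tsc22d3 (1.24 and 3.28, -1.42), and Cygb (0.293 and 0.730, -1.34). Of 6409 measured genes, 410 were at least 1.5-fold higher and 211 lower.

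**Figure D4:**
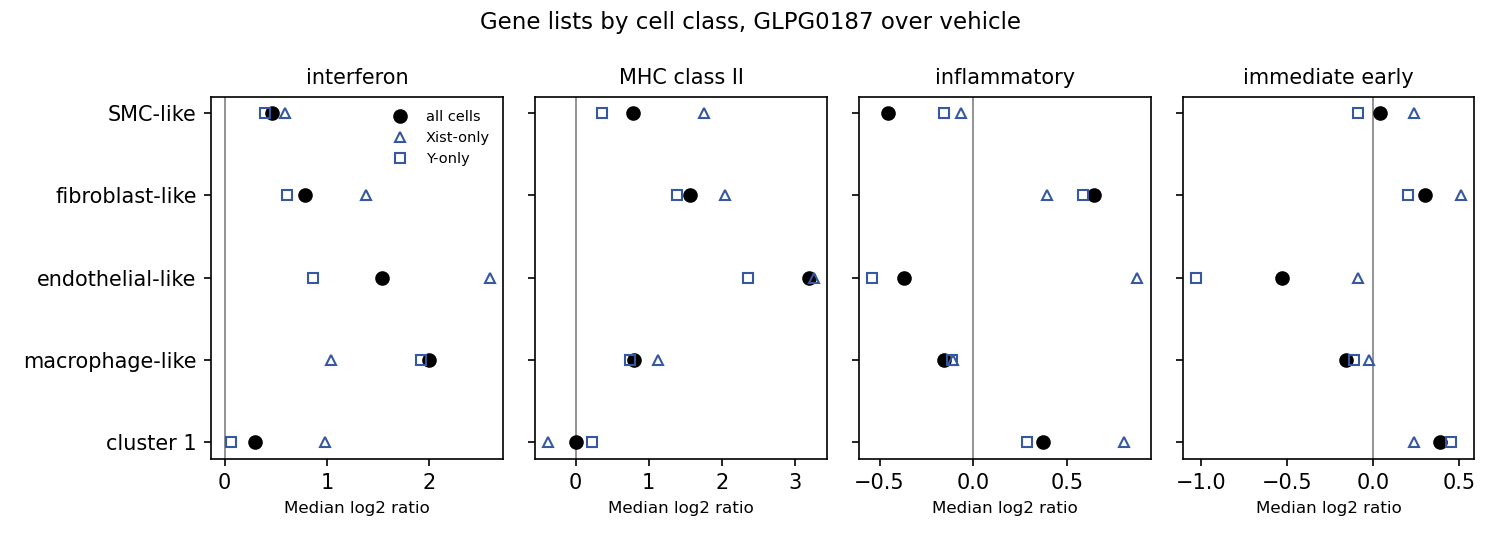
Median log2 ratio of GLPG0187 over vehicle (horizontal axis) of the interferon, MHC class II, inflammatory and immediate early lists in each class (vertical axis), for all cells, Xist-only cells and Y-only cells. Interferon medians ran from 0.29 in cluster 1 to 1.99 in macrophage-like cells, and the MHC class II median was 3.19 in endothelial-like cells.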

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

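Among the tests that follow, the share of macrophage-like cells with interferon genes and the clock genes that peak with Nr1d1 were fixed before their results were seen, and the others were chosen afterwards. The free-RNA test took the place of an earlier one on cluster 1, where many cells hold MHC class II transcripts in both libraries, and the glucocorticoid test was reworded after its first version, on SMC-like cells alone, had come out in favour of the explanation.

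Modulated SMC-like cells made up 4.52% and 18.2% of SMC-lineage cells, and a larger yield of contractile cells would dilute them only within that lineage, yet counted against fibroblast-like cells they were still lower, by -8.20 percentage points (-10.9 to -5.57), which argues against dilution as the whole cause. More tissue from the heart end of the aorta in the vehicle dissection stays open: outside the SMC lineage, cells with heart muscle RNA were fewer in the GLPG0187 library, at 5.40% and 7.10%, a difference of -1.70 points (-3.14 to -0.289), and clusters 1 and 6, which may hold root or valve cells, were larger in the vehicle library. Cells with heart muscle RNA were fewer in cluster 1 (4.76% and 7.74%), with an interval of the difference (-5.55 to -0.510) below 0. For cluster 6 (3.75% and 6.67%) and fibroblast-like cells (5.28% and 6.98%) the interval spanned 0. It also spanned 0 for endothelial-like (6.21% and 5.77%, 10 and 6 cells) and macrophage-like cells (5.87% and 5.06%, 20 and 9 cells), which are too few to decide. Among SMC-like cells, those with heart muscle RNA were more common (64.7% and 56.0%), mostly through Ryr2, which SMC also express (above 0 in 62.9% and 52.1%), while Myh6 had means of 0.0232 and 0.355 and cardiomyocyte markers a median of 0.18 in Y-only ones. The treatment named by the design may also account for the lower share, but with 1 pool per group it cannot be separated from dissection or animals.

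Interferon and MHC class II genes were higher in the GLPG0187 library in several classes. Free RNA would reach all classes alike, but in that library the share of cells with at least 3 MHC class II genes was 42.6 points (34.4 to 50.7) higher in endothelial-like than in fibroblast-like cells, which argues against free RNA as the source in endothelial-like cells and leaves it open for the low values elsewhere. A few strongly responding cells would leave the share of macrophage-like cells with at least 3 interferon genes nearly equal, but it was 16.7 points (10.5 to 23.6) higher, narrowly past the bound of 10 set in advance. As 96.5% and 79.8% of these cells met that mark, it cannot show which cells carry the large ratios. Rsad2 was above 0 in 37.5% and 11.8% of them, Ifit2 in 28.4% and 7.87%, and Cmpk2 in 19.4% and 3.93%. A strongly responding subset thus stays open for such genes. In SMC-like cells the share with at least 3 interferon genes was 18.6% and 15.7%, with an interval of the difference (-0.387 to 5.90) that spans 0, so a few cells may account for the difference there. A sub-cluster of SMC-lineage cells led by Ifit3, Isg15 and Ifit1 held 17 cells of the GLPG0187 library and 2 of the vehicle library. The list median was not recomputed without that sub-cluster. An infection or another immune difference between the cages or animals of the pools was not tested and stays open beside the treatment.

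Nr1d1, a clock gene, was higher in SMC-like cells of the GLPG0187 library (means 1.22 and 0.612), as it was in fibroblast-like cells (log2 ratio 0.66), cluster 1 (0.70) and cluster 6 (0.42). If tissue had been collected at another time of day, genes that peak with Nr1d1 would be higher. Over 7 such genes in SMC-like cells, from -0.41 to 0.49, the median was 0.029. Its interval over redrawn genes was -0.36 to 0.25. The prediction written in advance counted a median this small against time of day, although the interval is wide. Their medians elsewhere were -0.15 in fibroblast-like cells and -0.05 in cluster 1, but 0.56 over 4 genes in cluster 6 (0.16 to 0.92). Clock genes of the opposite phase had a median of -0.32 over 5 genes in SMC-like cells (-0.70 to -0.05). It was -0.20 in fibroblast-like cells, -0.23 in cluster 1 and -0.03 in cluster 6. Time of day thus stays open. A difference in stress hormone at collection would lower glucocorticoid-induced genes in every class. Their median was -0.68 in SMC-like, -0.24 in fibroblast-like, -0.55 in endothelial-like and -0.64 in macrophage-like cells and -0.31 in cluster 6, but 0.012 in cluster 1, and the list member Zbtb16 was higher in SMC-like cells (1.23) and in fibroblast-like cells (0.73). Tsc22d3, Fkbp5, Sgk1, Mt2 and Zbtb16 had been seen before the list was written, so this also stays open.

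Other results stood out because a list moved in opposite directions in cells of different sex or class, and none of these differences was tested. In SMC-like cells, medians of Xist-only minus Y-only cells differed by 0.40 for matrix proteases (0.14 and -0.26), by 0.41 for TGF-beta targets (0.14 and -0.26) and by 0.33 for immediate early genes (0.24 and -0.09). The endothelial activation list differed by -1.20 between SMC-like (-0.86, or -0.30 without modulated cells) and endothelial-like cells (0.33, but -0.04 in Y-only ones), and the modulated SMC list by -0.82 between the same classes (-0.49, or -0.20 without modulated cells, and 0.34, or 0.01 in Xist-only ones). The inflammatory list differed by -1.10 between SMC-like (-0.46) and fibroblast-like cells (0.64) and by 1.01 between fibroblast-like and endothelial-like cells (-0.37). That last contrast turned over in Xist-only cells, where the medians were 0.39 and 0.88.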

How the results depend on the processing

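The settings without modulated SMC-like cells, without clusters 1 and 6 and without the sub-cluster found in the vehicle library alone were added after seeing the data; the others were planned. A share or list median stayed the same if it lay within the interval of its main value, a log2 ratio if within 0.32 and a gene count if within 1.5-fold. A reversal was counted only for shares and list medians whose interval left out 0, lists outside the main comparisons also needing 0.32, and for genes at least 1.5-fold apart. Of 154 values that answer a comparison, 139 stayed the same, 15 moved and 0 reversed by this rule, while 5 had the opposite sign. These 139, and the 3366 given below, include the values of 2 cell filters that removed no cell and so could not move. Over all alternatives, GLPG0187 minus vehicle was 8.42 to 14.3 points for the SMC-like share and -16.4 to -8.15 points for the modulated share. The TGF-beta target median lay between -0.19 and 0.09 with members measured anew in each setting, or from -0.26 in Y-only to 0.14 in Xist-only cells with the same members throughout. The fibrillar collagen median lay between -0.04 and 0.12 and the mTORC1 median between -0.03 and 0.05, so these have no settled direction. With doublets kept the modulated difference was -10.3 points and Il6 stood at 0.30, and with genes scaled within each library the difference was -9.67 points (15.8% and 25.5%) and Ifit3 stood at -0.28. At resolution 1.0, Ifit3 stood at -0.17 and Enpp2 in endothelial-like cells at 0.064. In Xist-only cells the SMC-like difference was 14.3 points, the modulated difference -8.15 points, the macrophage-like difference -0.052 points, the contractile median 0.17 in SMC-like and -0.64 in macrophage-like cells, and the log2 ratios of Mmp2, Mmp3, Il6 and Tnfaip3 were 0.18, 0.55, 0.10 and -0.18. Median-of-ratios scaling gave a contractile median of 0.32, which is its uniform shift of 0.04. For all of these other than the scaling, the cause was not tested. Lower minimum values and thinning let sparser genes or noisier sums pass by construction: 195 genes were higher and 683 lower at a minimum of 30, 531 and 2203 at a minimum of 1 in each library, and 437 and 1022 with cells thinned to 2000. Without modulated cells, which carry the list's genes, the contractile median was 0.12, the modulated SMC median -0.20, the lower genes 184, Timp1 0.077 and Fbln2 0.34. Of 3616 other values, 3366 stayed the same, 238 moved and 12 reversed by the rule, all 12 given above. In all, 142 of them had the opposite sign, most of them small, such as Klf4 at 0.11 in Xist-only cells. Of the 3616 values, 2274 belong to named genes, list members and always-named genes included. Genes named by rank were chosen to keep their direction in Xist-only cells, in Y-only cells and under median-of-ratios scaling. They could therefore not reverse in those settings, and their agreement there says nothing on stability. The 2 other cell filters removed no cell and say nothing on stability, and the alternative planned for log-normalised files was not run because it does not apply. No paired analysis was possible because each group holds 1 library. Raw depth per cell is unknown, so it is not known how far shallow cells limit these values.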

Other observations

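Cluster 1, the largest cluster without a name, held 882 and 711 cells and differed between the libraries in immune and early response genes, chosen for mention after their values were seen. Immediate early genes were higher by a log2 ratio of at least 0.32 in 8 of 15 members (median log2 ratio 0.39), inflammatory genes in 6 of 12 (0.37) and interferon genes in 6 of 12 (0.29), while all 6 measured MHC class II genes lay between (0.01). Iigp1, an interferon-induced GTPase gene, had means of 3.27 and 1.12 (1.56), Gbp2 1.23 and 0.526 (1.23), the early response gene Fosb 7.19 and 3.55 (1.03) and Areg, a growth factor gene, 0.866 and 0.326 (1.42). The chemokine gene Ccl19 (0.867 and 1.49, -0.76) and Tnnt2 (1.35 and 2.40, -0.82) were lower. Haemoglobin genes among the erythroid markers had a median of 7.58 in this cluster but -0.63 in its Xist-only cells.

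Within modulated SMC-like cells, on 76 and 154 cells, several fibrillar collagen and proteoglycan genes were higher in the GLPG0187 library. Fibrillar collagen genes were higher in 6 of 12 members (median 0.37, or 0.18 in Xist-only cells) and proteoglycan genes in 5 of 8, with 1 lower (0.39). Higher members also numbered 2 of 14 elastic fibre genes (0.07), 3 of 11 basement membrane genes (0.14) and 3 of 8 matrix protease genes, with 1 lower (0.15, or 1.02 in Xist-only cells), and the lists were not tested against each other. Dcn, which encodes decorin, had means of 32.4 and 13.9 (1.22), the cartilage cytokine gene Cytl1 29.2 and 12.4 (1.24), and the MHC class I genes H2-K1 4.25 and 1.89 (1.17) and H2-D1 7.14 and 3.21 (1.16). The metallothionein gene Mt2 (2.84 and 6.80) and the kinase gene Sgk1 (0.961 and 2.24, -1.20) were lower, and immediate early genes were lower in 8 of 15 (-0.37, but 0.79 in Xist-only and -0.67 in Y-only cells). Fixed fibroblast markers were higher too, in 5 of 8 (0.43), and the Xist-only medians rest on 13 and 28 cells.

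Cells with at least 2 cycling markers above 0 made up 1.10% (0.815 to 1.46, 48 cells) of the GLPG0187 library and 0.543% (0.311 to 0.881, 16 cells) of the vehicle library. A sub-cluster of SMC-lineage cells led by Actc1, Ablim1 and Kcnk3 held 34 cells of the vehicle library, 31 of them Xist-only, and 0 of 1681 cells of the GLPG0187 library, which allows a share of up to 0.178% by the 3-cell rule and 0.219% by the exact interval. With 1 library per group, such a cluster cannot be told apart from a feature of that library.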
